A study of Arabidopsis thaliana with 71 samples.

How the data were processed

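The samples were Arabidopsis thaliana seedlings of the Columbia accession, grown for 7 days in liquid medium and then given 50 µM dexamethasone. Tissue was frozen before the hormone was added (0 min) and 30, 60 and 120 min after it. The 4 transgenic lines were followed beside wild type (WT). Each carried a transcription factor joined to the hormone-binding part of the glucocorticoid receptor (GR), which keeps a fusion protein out of the nucleus until dexamethasone is added. The factors were ASYMMETRIC LEAVES 2 (AS2), SHOOT MERISTEMLESS (STM), REVOLUTA (REV) and KANADI1 (KAN1). Total RNA was copied from its poly(A) end and sequenced on an Illumina instrument, per the labels' protocols.

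The deposited values are FPKM (fragments scaled by transcript length and library size) with Cufflinks' geometric normalization between libraries, per the labels. TopHat2 2.0.10 and Cufflinks are named as mapping and quantification tools, and TAIR10 as the genome build, per the submitters' processing notes. The Cufflinks version and whether strand was used are not given in the sources used here, so reads from overlapping genes may be shared between them. The table held 22346 entries, of which 14 were placeholder identifiers and were left out, so that 22332 genes remained. The table held 0 columns of other samples. Of the gene identifiers, 22041 matched a locus tag of the TAIR10.1 reference, which gave symbols and coordinates, and 291 did not match and kept their identifier. Coordinates below are those of TAIR10.1, since the deposited table has none.

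Depth per library is unknown: FPKM keep no read totals, and low values did not fall on whole multiples of 1 read. The share of low values at their most common ratio to the first library of the same code series had a median of 2.26% in Ot79, 7.38% in Ot86 and 4.62% in OtA0. No counting interval could therefore be given, and the precision of every value is that of the replicates. The median FPKM over genes was 4.25 to 4.92 per library, and 332 to 1136 genes were listed at 0 in a library. Among genes with a median above 20 FPKM, 31 were listed at 0 in at least 1 library, so a 0 can be a failed estimate. Genes shorter than 150 bp took 0.04% to 95.81% of the FPKM total in code series Ot79, so the totals were not used as a measure of depth. The main axis of the residuals held 15.1% of their variance and had a correlation of 0.636 (absolute) with log10 FPKM total. GR-AS2 0 min replicate 1, GR-AS2 60 min replicate 3, GR-STM 0 min replicate 2, GR-REV 0 min replicate 3 and GR-KAN1 0 min replicate 3 stood furthest out on it.

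Groups were taken from the labels as line and time, giving 20 groups and 71 libraries. WT had 6 libraries at each time and the GR lines 3, except GR-REV at 30 min with 2. The series' design text calls all replicates biological. WT replicates 4 to 6 carry library codes of later series (Ot86 or OtA0) and all other libraries those of series Ot79. Replicate numbers are shared across groups but do not pair the samples by any label.

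Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), over the 19406 genes whose highest group mean was at least 1 FPKM. One linear model held all libraries, with a mean per group and the library code series as a covariate. It had 49 residual degrees of freedom and used the empirical Bayes step with a trend on mean level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, in a two-sided test. The comparisons were WT at each time against WT at 0 min, each GR line against WT at 0 min, each GR line's change from 0 min minus that of WT at the same time ("beyond WT"), and the change of GR-REV at 120 min minus that of GR-KAN1, 20 comparisons in all. Log2 changes are on the log2(FPKM + 0.5) scale, which understates changes of low genes, and are printed with their standard error (SE). Levels are printed as mean FPKM ± SD with n libraries. A model log2 change takes the code series into account and need not equal the ratio of the means.

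Before the data were examined, 24 gene lists with 226 members were fixed, of which 11 members were not in the table. They were HD-ZIP III, KNOX, LITTLE ZIPPER, HD-ZIP II and shade response, abaxial identity, meristem and organ boundary, described REV and KAN1 targets, auxin-induced genes, auxin transport, abscisic acid receptors and response, brassinosteroid metabolism, cytokinin metabolism, gibberellin metabolism, type-A response regulators, cell cycle, xylem differentiation, jasmonate response, touch and early stress, heat shock, xenobiotic response, circadian clock, photosynthetic markers, root markers and seed storage. The described targets come from published work on these factors, part of it on GR lines of this kind, so that list is not independent evidence of its direction. List shifts were tested with limma's camera and an estimated correlation between members, adjusted over the lists within a comparison, and a preset correlation of 0.01 was an alternative. Counts of members "adjusted over the list alone" use the adjusted p within that list.

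Genes are named by a rule fixed in advance. It takes the 4 targeted genes in every line. At 120 min it takes the 10 highest and 10 lowest log2 changes among called genes with a mean of at least 5 FPKM in the line's 0 or 120 min group and no overlap between those libraries. At 30 and 60 min and before dexamethasone it takes 5 each way by the same conditions. For GR-REV against GR-KAN1 it takes 10 each way with at least 5 FPKM in 1 of the 4 groups. From each list it takes up to 4 members with the smallest p. Genes with no symbol are mostly left unnamed.

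The fit was tested on simulated data for the comparison of GR-STM beyond WT at 120 min over 19406 genes. Noise was drawn from a normal distribution with each gene's residual SD, independently between genes and libraries. The fit recovered 8 of 67 genes changed 1.5-fold, 34 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 12 unchanged genes called. In this setting most changes under 2-fold were out of reach. Deviations shared by many genes of a library were not simulated, so the 12 calls of unchanged genes need not hold for the real libraries.

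The alternatives were a pseudocount of 1 or 0.1, no filter on low values, a filter at a mean of 5 FPKM, no code series covariate, WT replicates 4 to 6 left out, replicate blocks, quantile normalization, fits of only the groups compared, and each library left out in turn. Added after seeing the data were the overlap of called lists in 100 simulated sets with no effect, made by shuffling residuals between libraries and taking lists of the same sizes, the log10 FPKM total as a covariate, the fit without the 2 libraries least like the rest (GR-AS2 30 min replicate 3 and GR-REV 0 min replicate 3), the leaving out of each library for named genes and called lists, and a correlation of changes with no WT library shared. Other splits of the libraries into groups of the same sizes were drawn to see how often they call as many genes.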

Results

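Gene expression was measured by RNA sequencing in 71 libraries of whole Arabidopsis seedlings from 5 lines at 4 times. WT was sequenced in 6 libraries at each of 0, 30, 60 and 120 min of dexamethasone. GR-AS2, GR-STM, GR-REV and GR-KAN1 were sequenced in 3 libraries at each time, except GR-REV at 30 min with 2. AS2 is a LOB-domain protein of the upper leaf side, STM a KNOX homeodomain protein of the shoot meristem, REV an HD-ZIP III protein of the upper leaf side, and KAN1 a GARP protein of the lower leaf side. The series asks which genes respond when each factor is moved to the nucleus. Depth is unknown, so the precision of every value below is that of its replicate libraries.

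Each line carried high levels of the gene it was named for, at every time. AS2 (AT1G65620, chromosome 1, 24398143 to 24400989) stood at 199.5 ± 83.3 FPKM (SD, n = 12) over the GR-AS2 libraries and at 3.99 ± 1.31 FPKM (n = 24) in WT. STM (AT1G62360, chromosome 1, 23058582 to 23062063) stood at 137 ± 78.2 FPKM (n = 12) in GR-STM and 2.96 ± 0.636 FPKM in WT. REV (AT5G60690, chromosome 5, 24396981 to 24402195) stood at 97.4 ± 40.9 FPKM (n = 11) in GR-REV and 3.63 ± 1.16 FPKM in WT. KAN1 (AT5G16560, chromosome 5, 5406863 to 5411766) stood at 214 ± 109 FPKM (n = 12) in GR-KAN1 and 2.51 ± 0.582 FPKM in WT. Reads of the transgene and of the native gene are summed in these values. Before dexamethasone the differences from WT on the log2 scale were 6.51 (SE 0.18) for AS2, 5.61 (SE 0.27) for STM, 4.91 (SE 0.27) for REV and 5.76 (SE 0.28) for KAN1. Targeted genes also moved in lines other than their own. In GR-STM, KAN1 went from 2.69 ± 0.237 FPKM at 0 min to 6.999 ± 0.0858 FPKM at 60 min (n = 3 each). WT had 2.69 ± 0.746 and 2.57 ± 0.646 FPKM (n = 6 each). REV went from 3.55 ± 0.503 to 6.45 ± 0.819 FPKM in GR-STM, with 4.28 ± 1.49 and 3.84 ± 0.868 FPKM in WT. These changes were not called. In lines other than its own, a targeted gene passed limma's test beyond WT in a single case. AS2 fell by 0.95 on the log2 scale in GR-KAN1 at 60 min (SE 0.24, limma adjusted p = 0.0315), a call that was lost in 7 of the 18 fits without a single library and was not made at 120 min (-0.84, adjusted p = 0.124).

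**Figure D1:**
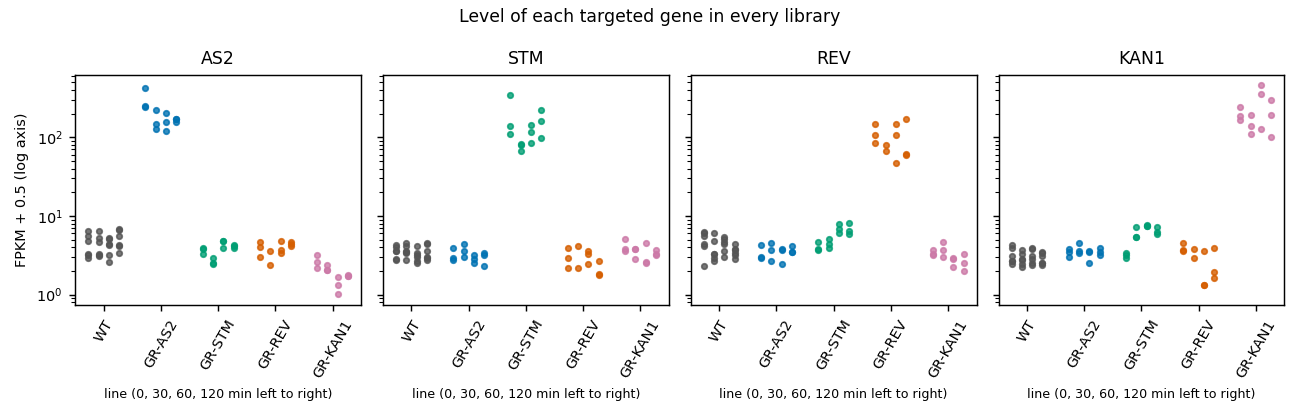
FPKM of AS2, STM, REV and KAN1 in every library (vertical axis, FPKM + 0.5 on a log scale) against line of seedlings with times left to right (horizontal axis), points being libraries. Each gene is high in the line named for it, as for KAN1 with 99.4 to 462 FPKM in GR-KAN1 and 1.73 to 3.79 FPKM in WT.

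In WT seedlings few genes passed the test after dexamethasone, and no mock-treated group was sequenced, so hormone, handling and elapsed time are not separated in these changes. MYB4, a repressor of phenylpropanoid genes, rose from 11.2 ± 1.69 FPKM at 0 min to 24.2 ± 3.46 FPKM at 30 min (SD, n = 6 each), a log2 change of 0.90 (SE 0.12, limma adjusted p = 6.17e-06). It stayed higher at 60 min by 0.89 (SE 0.11) and at 120 min by 0.79 (SE 0.13). AT3G13310 rose by 1.95 (SE 0.30) at 60 min and 2.51 (SE 0.36) at 120 min on the log2 scale, and AT2G44130 by 2.02 (SE 0.17) and 2.47 (SE 0.20). HFR1, a bHLH protein of shade responses, fell by 1.47 on the log2 scale at 120 min (SE 0.24, adjusted p = 0.00044). IGMT2, a methyltransferase of indole glucosinolates, rose by 2.40 (SE 0.50) at 30 min, 2.29 (SE 0.46) at 60 min and 2.5 (SE 0.55) at 120 min. The IGMT2 calls held in 4, 2 and 3 of the 12 fits without a single library at these times, and its SD at 30 min was 20.6 FPKM against 1.44 FPKM at 0 min. CYP81F2, a cytochrome P450 of the same pathway, rose by 2.27 (SE 0.46) at 120 min, and this call was lost without WT 0 min replicate 2 or WT 120 min replicate 2 or 3 (highest adjusted p = 0.147).

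In all, 5 genes rose and 6 fell in WT at 30 min, 5 rose and 0 fell at 60 min, and 11 rose and 2 fell at 120 min in limma's test. At an unadjusted p under 0.05 there were 1002, 792 and 1619 genes, where 970 would be called by chance. The counts were unsteady. At 30 min 11 became 1 without WT 0 min replicate 2, WT 30 min replicate 2 or WT 30 min replicate 3, 2 without WT 0 min replicate 1, 3 without WT 0 min replicate 3, 5 without WT 30 min replicate 4, 6 without WT 0 min replicate 4 or 5 and 19 without WT 30 min replicate 6. At 60 min 5 became 3 without WT 0 min replicate 1, 2, 3, 4 or 5 or WT 60 min replicate 2, 4, 5 or 6 and 9 without WT 60 min replicate 3. At 120 min 13 became 8 without WT 0 min replicate 1, 7 without WT 120 min replicate 3 and 5 without WT 120 min replicate 2. At 120 min 273 genes were called with no covariate for library code series, and WT replicates 4 to 6 at that time are all of a code series that WT 0 min lacks. Fits of only the groups compared moved the counts at all times, most at 120 min, as given in the part on processing. None of the 23 lists shifted in WT. The nearest was heat shock at 30 min, with a median log2 change of -0.93 and an adjusted p of 0.0775.

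In GR-AS2 before dexamethasone, PDF1.5, a plant defensin, was lower by 3.79 on the log2 scale (-3.79, SE 0.52, limma adjusted p = 7.55e-06), at 0.522 ± 0.904 FPKM against 13.0 ± 3.47 FPKM (n = 3 and 6). Its SD exceeded its mean, so values at or near 0 were among the 3 libraries, and a listed 0 can be a failed estimate. YAB3, a YABBY protein of the lower leaf side, was lower (-0.92, SE 0.17, adjusted p = 0.00127). OSM34, an osmotin-like protein, stood at 335 ± 156 FPKM against 35.2 ± 14.9 FPKM (log2 difference 3.1, SE 0.68, adjusted p = 0.00343). NIT2, a nitrilase, was higher by 3.05 (SE 0.69). Of the 6 cell cycle genes 3 were lower and 0 higher, 5 lower when adjusted over the list alone, and the list was not shifted (median -0.56, camera adjusted p = 0.265). The 3 were KNOLLE, a syntaxin of the cell plate, at -0.94, the cyclin gene CYCD3;1 at -0.69 and the mitotic kinase gene CDKB2;1 at -0.55. AS1, the MYB partner of AS2, was lower (-0.84), and no other list was shifted in this comparison. A pair of neighbouring genes, AT4G19239 and AT4G19240, stood at 17.0 ± 6.77 and 5.74 ± 0.938 FPKM in GR-AS2 and were listed at 0 in every WT library.

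In GR-AS2 before dexamethasone, 913 genes were higher and 1087 lower, and 5271 had an unadjusted p under 0.05. The count depended strongly on which library was left out: 2000 genes became 25 without GR-AS2 0 min replicate 3, 1161 without replicate 2 and 3279 without replicate 1. On the main axis of the residuals replicate 1 stood apart, at -56.9, with replicates 2 and 3 at 28.15 and 28.75. The fit without replicate 3 thus leaves 2 unlike libraries. Without replicate 3 the adjusted p was 0.0778 for OSM34, 0.0964 for NIT2, 0.112 for KNOLLE, 0.122 for CYCD3;1 and 0.131 for AS1, while PDF1.5, YAB3 and the pair of neighbouring genes passed in every such fit. The count was 304 with WT replicates 4 to 6 left out and 114 in a fit of only the groups compared.

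In GR-STM before dexamethasone, genes of rapid stress responses were higher. ERF5 and ERF6, ethylene response factors, differed by 1.85 (SE 0.33) and 2.28 (SE 0.41) on the log2 scale. ZAT10, a zinc finger repressor of stress responses, differed by 2.52 (SE 0.52, limma adjusted p = 0.00835), at 30.6 ± 23.9 FPKM against 2.75 ± 1.19 FPKM (n = 3 and 6). Of the 11 genes of the touch and early stress list, 5 were higher and 0 lower, and 9 were higher when adjusted over the list alone, with a median difference of 1.59 (camera adjusted p = 0.00174), a call that was lost in a fit of only the groups compared (adjusted p = 0.756). AT1G29560 was higher by 4.98 (SE 0.28) at 28.9 ± 20.5 FPKM against 0.426 ± 0.129 FPKM. In all, 64 genes were higher and 0 lower, and 1226 had an unadjusted p under 0.05 in limma. The count was 4 without GR-STM 0 min replicate 3, 5 without replicate 2, 165 without replicate 1, 41 without WT 0 min replicate 1 and 42 without WT 0 min replicate 3, and the calls of ERF5, ERF6 and ZAT10 were lost without GR-STM replicate 2 or 3. Those of STM and AT1G29560 were kept in each of these fits, as was that of the list (highest adjusted p = 0.0315). The count was 137 with no code series covariate, 15 with WT replicates 4 to 6 left out, 99 without the pair of least typical libraries and 4 in a fit of only the groups compared.

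In GR-REV before dexamethasone, PDF1.2, a defensin induced by jasmonate, stood at 8025 ± 2131 FPKM against 74.0 ± 54.2 FPKM in WT (SD, n = 3 and 6), a log2 difference of 6.30 (SE 0.80, limma adjusted p = 6.30e-08). NATA1, an acetyltransferase that makes acetylornithine, stood at 664 ± 356 FPKM against 3.4 ± 1.41 FPKM, a difference of 6.98 (SE 0.88). The defensin genes PDF1.2c, PDF1.3 and PDF1.2b were higher by 6.44 (SE 0.77), 5.47 (SE 0.73) and 5.18 (SE 0.81), and reads shared between these close copies were not separated here. FRO6, a ferric reductase, was lower (-1.62, SE 0.29), and TGG2, a myrosinase, was lower (-1.67, SE 0.43), the latter not without GR-REV 0 min replicate 3 (adjusted p = 0.0573). All 7 genes of the jasmonate list were higher, also when adjusted over the list alone, with a median difference of 2.22 (camera adjusted p = 1.78e-04), a call that was lost in a fit of only the groups compared (adjusted p = 0.0786). They included the repressor genes JAZ8, at 2.86 (SE 0.38), and JAZ10, at 2.39 (SE 0.28), and the lipoxygenase genes LOX2, at 2.64 (SE 0.31), and LOX3, at 1.87 (SE 0.21). The glutathione transferase genes GSTF6 and GSTF7 were higher by 3.08 and 3.36, while the xenobiotic list was not shifted. In all, 943 genes were higher and 572 lower, and these 1515 became 760 without GR-REV 0 min replicate 3 and 991 without replicate 1. With no code series covariate 2410 genes were called, and 826 with WT replicates 4 to 6 left out, 984 among genes with a mean of 5 FPKM or more, 942 without the pair of least typical libraries and 573 in a fit of only the groups compared.

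In GR-KAN1 before dexamethasone, NRT1.1, a nitrate transporter and sensor, was lower at 11 ± 1.07 FPKM against 49.0 ± 1.52 FPKM (log2 difference -2.10, SE 0.23, limma adjusted p = 1.20e-08, n = 3 and 6). NRT1.8, another nitrate transporter, was lower (-2.0, SE 0.35), as was ACD6, an ankyrin protein of defence (-2.41, SE 0.45). GA2OX2, an enzyme that inactivates gibberellins, was higher by 1.38. Touch and early stress genes were higher, with TCH4, a xyloglucan endotransglucosylase, at 29.8 ± 2.67 FPKM against 8.25 ± 2.20 FPKM (1.85, SE 0.34) and ERF6 higher by 2.16 (SE 0.41). Of the 11 genes of that list 5 were higher and 0 lower, 8 when adjusted over the list alone, with a median difference of 1.51 (camera adjusted p = 0.00812), lost in a fit of only the groups compared (adjusted p = 0.450). MRD1 and HEI10 were higher by 3.80 (SE 0.25) and 3.70 (SE 0.17). The annotated bounds of these genes overlap and strand use is not given, so it is uncertain which of them the reads come from. In all, 101 genes were higher and 43 lower, and 144 became 45 without GR-KAN1 0 min replicate 3, 56 without replicate 2, 84 without WT 0 min replicate 1 and 95 without WT 0 min replicate 3. The count was 308 with no code series covariate, 43 with WT replicates 4 to 6 left out and 80 among genes with a mean of 5 FPKM or more.

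The changes from 0 min in each GR line were then compared with those of WT. In GR-AS2, 2 genes passed the test beyond WT over the 3 times. AT4G27900 was 17.3 ± 0.728 FPKM at 60 min and 6.99 ± 0.871 FPKM at 0 min (SD, n = 3 each), while WT had 6.86 ± 2.22 and 7.06 ± 1.52 FPKM (n = 6 each), a change beyond WT of 1.34 (SE 0.22, limma adjusted p = 0.00277). PDF1.5 was low in this line before dexamethasone, with values at or near 0 FPKM that can be failed estimates. From that start it rose beyond WT by 3.65 at 60 min (SE 0.69, adjusted p = 0.0230), which 12 of 18 fits without a single library kept. These were the only 2 genes called at 60 min, and 0 genes were called at 30 and 120 min in limma's test, with 2049, 1713 and 1308 genes at an unadjusted p under 0.05 at 30, 60 and 120 min. The count at 30 min was 387 without GR-AS2 30 min replicate 2, 138 without GR-AS2 0 min replicate 1 and 30 without GR-AS2 30 min replicate 1. At 60 min it was 27 without GR-AS2 0 min replicate 1, 6 without WT 60 min replicate 6 and 1 without WT 0 min replicate 3, WT 60 min replicate 4, GR-AS2 0 min replicate 3 or GR-AS2 60 min replicate 1 or 2, and at 120 min 1 without GR-AS2 0 min replicate 1. The count at 60 min also moved with no code series covariate, quantile normalization or only the groups compared, as given in the part on processing. None of the 23 lists shifted in GR-AS2 at any time.

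**Figure D2:**
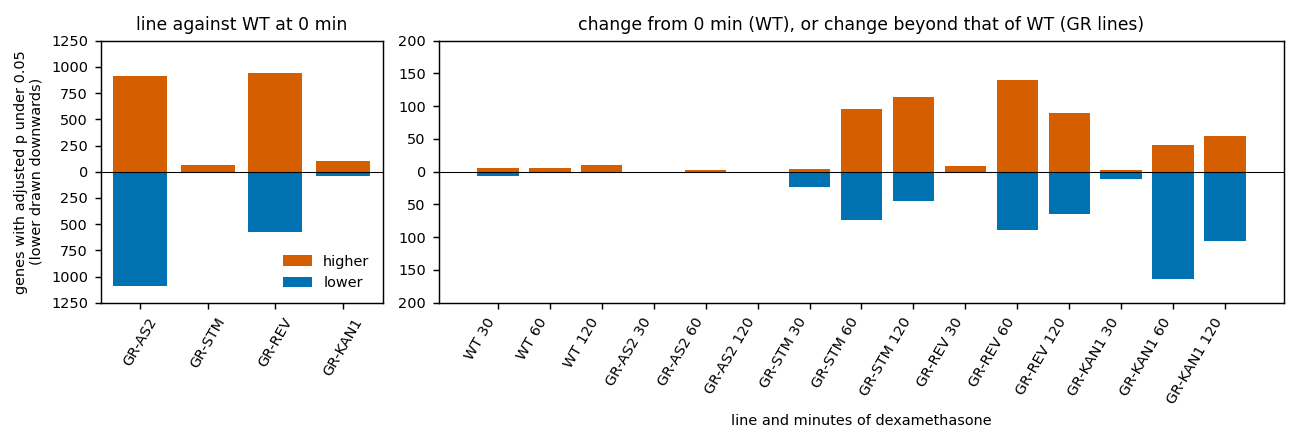
Number of genes called higher (bars upward) and lower (bars downward) with a limma adjusted p under 0.05 (vertical axis) in each line at 0 min against WT, and by line and minutes of dexamethasone (horizontal axis). GR-AS2 has 2000 genes before dexamethasone and 0, 2 and 0 beyond WT after it, while GR-STM has 64 before and 28, 170 and 159 after.

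In GR-STM, NTM1 (AT4G01540, chromosome 4, 670483 to 672789), a membrane-bound NAC transcription factor, rose from 2.96 ± 0.621 FPKM at 0 min to 44.5 ± 12.9 FPKM at 60 min and 50.7 ± 1.45 FPKM at 120 min (SD, n = 3 each). WT had 1.91 ± 0.483 and 1.91 ± 0.411 FPKM (n = 6 each) at 0 and 120 min, so that the change beyond WT was 3.87 at 120 min (SE 0.36, limma adjusted p = 2.82e-11). The NTM1 gene is in none of the lists. CUC1 (AT3G15170, chromosome 3, 5109782 to 5111608), a NAC factor that sets organ boundaries, rose from 0.349 ± 0.116 FPKM to 9.98 ± 2.68 FPKM at 120 min, by 3.72 beyond WT (SE 0.34, adjusted p = 1.83e-11). Of the 11 genes of the meristem and organ boundary list 3 rose and 0 fell at both 60 and 120 min, also when adjusted over the list alone. These were CUC1, AS1 and BOP2, a boundary gene of the BTB-ankyrin family. The list's median changes were 0.35 (camera adjusted p = 0.00308) and 0.45 (adjusted p = 5.43e-04), and both calls were lost in fits of only the groups compared (adjusted p = 0.0781 and 0.384). AS1 rose by 1.78 (SE 0.25) and 1.47 (SE 0.27), and BOP2 by 1.37 (SE 0.22) and 1.04 (SE 0.23), the last not without GR-STM 0 min replicate 2 (adjusted p = 0.0640).

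ATHB2, an HD-ZIP II protein induced by shade, had the smallest adjusted p in GR-STM at 30 min, at 22.7 ± 6.76 FPKM against 5.51 ± 1.23 FPKM at 0 min (2.16 beyond WT, SE 0.26, limma adjusted p = 7.74e-07). It stayed higher by 1.76 at 60 min and 1.69 at 120 min. CKX7, a cytokinin oxidase, rose by 1.5 at 60 min and 1.93 at 120 min, and the zinc finger gene ZFP1 by 2.39 (SE 0.31) at 60 min. At 120 min BGLU45, a beta-glucosidase, rose by 2.86 (SE 0.58), BCAT-2, a branched-chain aminotransferase, by 2.54 (SE 0.34), and CXE17, a carboxylesterase, by 3.69 (SE 0.38). Among genes lower at 120 min were the sucrose transporter gene SWEET12 (-1.70, SE 0.33), the glycerol phosphate acyltransferase gene GPAT3 (-1.80, SE 0.29) and TAA1, an enzyme of auxin synthesis (-1.04).

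The touch and early stress genes, which started high in GR-STM, fell beyond WT. TCH4 went from 27.2 ± 18.6 FPKM at 0 min to 5.18 ± 0.303 FPKM at 120 min while WT went from 8.25 ± 2.20 to 14 ± 3.94 FPKM (-2.39, SE 0.48, limma adjusted p = 0.00236). The high start was in 2 of the 3 libraries at 0 min, at 36.4 and 39.4 FPKM, while replicate 1 stood at 5.83 FPKM. The list's median change was -1.66 at 30 min (camera adjusted p = 0.00389), -1.97 at 60 min (adjusted p = 0.00896) and -1.31 at 120 min (adjusted p = 0.0223). In fits of only the groups compared the 3 calls were lost (adjusted p = 0.276, 0.215 and 0.384), and that at 120 min also with WT replicates 4 to 6 left out (adjusted p = 0.0823). Of its 11 genes 3, 6 and 1 fell and 0 rose at these times, and 10, 9 and 8 fell when adjusted over the list alone. The list's call was lost at 30 min without GR-STM 0 min replicate 2 (adjusted p = 0.0533), and at 120 min without GR-STM 0 min replicate 2, GR-STM 0 min replicate 3 or GR-STM 120 min replicate 2 (highest adjusted p = 0.185). RTFL12, a small peptide of the ROTUNDIFOLIA family, and ERF4, an ethylene response repressor, fell at 30 min (-3.03, SE 0.55, and -2.08, SE 0.37), not without GR-STM 0 min replicate 2 or 3 (highest adjusted p = 0.141 and 0.130).

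Beyond WT, 4 genes rose and 24 fell in GR-STM at 30 min, 96 rose and 74 fell at 60 min, and 114 rose and 45 fell at 120 min. Of the genes called at 60 min, 62 were called higher and 17 lower again at 120 min, and 0 the opposite way. Both times are set against the same 0 min libraries, and lists of these sizes from simulated data with no effect shared a mean of 9.93 and 4.49 genes and at most 45 and 14. The count at 30 min, 28, was 1 without GR-STM 0 min replicate 2 or 3, 105 without GR-STM 0 min replicate 1 and 51 without GR-STM 30 min replicate 3. It was 11 without WT 30 min replicate 6, 12 without WT 30 min replicate 2, 14 without WT 0 min replicate 1, 3 or 5 or GR-STM 30 min replicate 2, and 15 without WT 0 min replicate 6. At 60 min 170 became 90 without GR-STM 0 min replicate 2, 77 without GR-STM 0 min replicate 3 and 109 without GR-STM 60 min replicate 2. With WT replicates 4 to 6 left out the counts were 1, 42 and 95, and among genes with a mean of 5 FPKM or more 89 and 71 at 60 and 120 min.

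**Figure D3:**
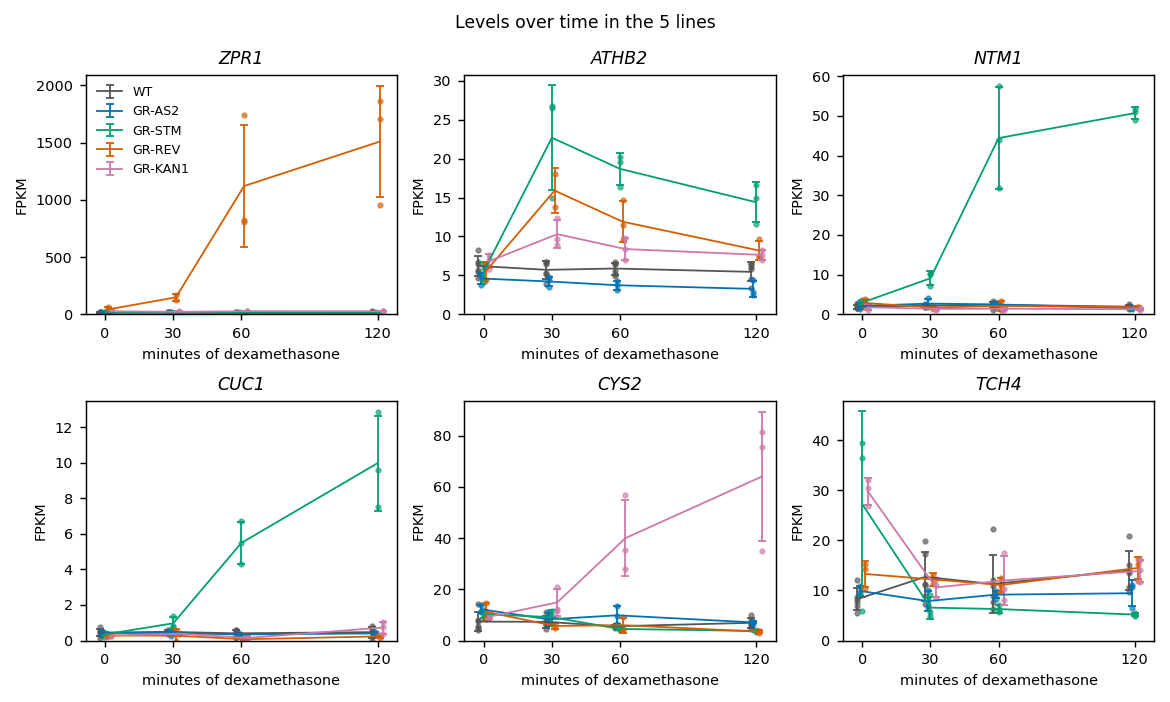
FPKM (vertical axis) over minutes of dexamethasone (horizontal axis) for ZPR1, ATHB2, NTM1, CUC1, CYS2 and TCH4 in the 5 lines, with points as libraries, drawn lines through the means and bars of 1 SD. ZPR1 reaches 1510 FPKM in GR-REV, NTM1 50.7 FPKM in GR-STM and CYS2 64.0 FPKM in GR-KAN1 at 120 min.

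In GR-REV at 60 min, the 3 highest changes were in genes of the LITTLE ZIPPER list, whose small proteins are known to bind HD-ZIP III factors. ZPR1 (AT2G45450, chromosome 2, 18733275 to 18734341), a LITTLE ZIPPER protein, rose from 41.5 ± 19.6 FPKM at 0 min to 148 ± 33.0 at 30 min, 1120 ± 535 at 60 min and 1510 ± 485 FPKM at 120 min (SD, n = 3, 2, 3 and 3). WT stayed between 12.5 ± 5.33 and 18.1 ± 4.98 FPKM (n = 6), and the change beyond WT was 5.43 at 120 min (SE 0.36, limma adjusted p = 1.69e-16). ZPR3 rose by 4.24 (SE 0.52) at 60 min and 3.75 (SE 0.55) at 120 min, and ZPR4, which TAIR10.1 annotates as a non-coding RNA, by 4.08 (SE 0.34) and 3.46 (SE 0.36). Of the 4 LITTLE ZIPPER genes 1, 3 and 3 rose at 30, 60 and 120 min and 0 fell, and 3, 4 and 4 rose when adjusted over the list alone. The list's median changes were 1.76 (camera adjusted p = 2.09e-05), 4.16 (adjusted p = 1.90e-10) and 3.6 (adjusted p = 1.12e-10). The call of ZPR1 at 30 min was lost without GR-REV 30 min replicate 2 (adjusted p = 0.0776), which leaves a lone library.

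Genes of the HD-ZIP II and shade list, all 12 of which lay below WT in GR-REV at 0 min (median -0.38) and 5 still at 60 min, were shifted up as well. HAT2, an HD-ZIP II protein, rose from 8.74 ± 1.54 FPKM to 28.7 ± 2.04 FPKM at 60 min (1.66 beyond WT, SE 0.23, limma adjusted p = 3.55e-06) and was 1.2 higher at 120 min (SE 0.24). HAT3, of the same family, rose by 1.72 (SE 0.26) at 60 min. TAA1 and YUC5, enzymes of auxin synthesis, rose by 1.48 (SE 0.20) and 1.46 (SE 0.27) at 60 min, and IAMT1, an auxin methyltransferase, by 2.41 (SE 0.46) at 120 min. Of the 12 genes of the HD-ZIP II and shade list 2, 6 and 3 rose at 30, 60 and 120 min and 0, 1 and 0 fell, the one being PIL1, a bHLH protein (-1.10). Adjusted over the list alone, 8, 7 and 8 rose and 0, 1 and 0 fell, and the median changes were 0.94 (camera adjusted p = 4.90e-05), 0.93 (adjusted p = 0.00440) and 0.88 (adjusted p = 0.00158). The genes that rose at 30 min were ATHB2, by 1.67 (SE 0.28), and HAT2, by 1.39 (SE 0.25), and both calls were lost without GR-REV 30 min replicate 1, which leaves a lone library.

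The list of described REV and KAN1 targets rose in GR-REV with medians of 1.2 at 30 min (camera adjusted p = 7.34e-10), 1.47 at 60 min (adjusted p = 6.43e-14) and 0.88 at 120 min (adjusted p = 3.62e-10). Of its 12 genes 3, 10 and 5 rose and 0 fell, and 8, 10 and 10 rose when adjusted over the list alone, which is not independent evidence because part of the list was described in lines of this kind. Of its members, ZPR1 and ZPR3 are also in the LITTLE ZIPPER list and HAT2, HAT3, ATHB2, ATHB4, TAA1 and YUC5 in the HD-ZIP II and shade list, so the shifts of these lists are not separate results. It includes PYL6, an abscisic acid receptor, which rose by 1.98 (SE 0.28) at 60 min. Of the 5 brassinosteroid genes 1 rose and 1 fell at 60 and at 120 min, with the list not shifted (camera adjusted p = 0.697 and 0.284). These were the synthesis enzymes DWF4, at 0.97 and 1.03, and BR6OX2, at -1.46 and -1.21. GA3OX1, an enzyme of gibberellin synthesis, rose by 1.58 at 60 min. HB6, an HD-ZIP I protein of abscisic acid responses, was lower at 60 min, at 24.5 ± 3.36 FPKM against 72.5 ± 9.07 FPKM (-1.76, SE 0.19, limma adjusted p = 2.81e-09, n = 3 each). At 120 min SAG29, a SWEET sugar transporter, rose by 2.80 (SE 0.54) and the nitrate transporter gene NRT1.7 was lower (-1.85, SE 0.37).

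Beyond WT, 8 genes rose and 0 fell in GR-REV at 30 min, 140 rose and 89 fell at 60 min, and 90 rose and 65 fell at 120 min. Among these, 60 higher and 19 lower genes were shared by 60 and 120 min, which use the same 0 min libraries, and 0 were called the opposite way. In simulated data with no effect such lists shared a mean of 10.9 and 6.80 genes and at most 50 and 20. At 30 min 8 became 16 without GR-REV 0 min replicate 2, and fits without a GR-REV 30 min library leave 1 there and are not counted. At 60 min 229 became 134 without GR-REV 0 min replicate 3, and at 120 min 155 became 97 without GR-REV 120 min replicate 1, 103 without GR-REV 120 min replicate 3 and 101 without GR-REV 0 min replicate 3. With WT replicates 4 to 6 left out the counts were 4, 77 and 68, among genes with a mean of 5 FPKM or more 3, 119 and 87, and in fits of only the groups compared 2, 112 and 84.

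In GR-KAN1, more genes fell than rose. RTFL12 fell at all 3 times, from 14.4 ± 1.74 FPKM at 0 min to 1.07 ± 0.588 FPKM at 30 min (SD, n = 3 each; -3.82 beyond WT, SE 0.55, limma adjusted p = 1.23e-04), and was lower by 3.05 and 3.37 at 60 and 120 min (-3.05, SE 0.54, and -3.37, SE 0.57). CAF1a, a deadenylase of mRNA decay, fell at 60 min (-2.40, SE 0.40) and 120 min (-2.10, SE 0.42), and CRK30, a receptor-like kinase, at 120 min (-1.94, SE 0.34). CYS2 (AT2G31980, chromosome 2, 13609093 to 13609955), an inhibitor of cysteine proteases, rose from 9.31 ± 0.989 FPKM to 40.0 ± 14.9 FPKM at 60 min and 64.0 ± 25.4 FPKM at 120 min, by 3.01 beyond WT (SE 0.39, adjusted p = 2.00e-06). GA20OX3, an enzyme of gibberellin synthesis, rose by 1.21 at 60 min and 2.42 at 120 min, while the gibberellin list as a whole did not shift. MES10, a methylesterase, rose by 1.74 (SE 0.34) and SQP1, a squalene epoxidase, by 2.00 (SE 0.36) at 120 min.

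Genes that rose in GR-REV were among those that fell in GR-KAN1. HAT2 fell at 60 min from 12.3 ± 0.532 FPKM to 4.71 ± 0.778 FPKM (n = 3 each; -1.32 beyond WT, SE 0.23, limma adjusted p = 2.60e-04), and PYL6 fell too (-1.48, SE 0.28, adjusted p = 0.00110). Of the 12 described REV and KAN1 targets 3 fell and 0 rose at 60 min, the other one being AS2, and 2 fell and 0 rose at 120 min. Adjusted over the list alone 5 and 4 fell, and the medians were -0.51 (camera adjusted p = 0.0158) and -0.42 (adjusted p = 0.0466). The call at 60 min was lost without GR-KAN1 60 min replicate 2 (adjusted p = 0.0507), and that at 120 min in 12 of 18 fits without a single library (highest adjusted p = 0.174) and in a fit of only the groups compared (adjusted p = 0.0912). Of the 13 auxin-induced genes 1 fell and 0 rose at 120 min, IAA2 (-1.18, SE 0.26), and 5 fell when adjusted over the list alone, with a median of -0.72 (camera adjusted p = 0.0466). That list's call was lost in 8 of 18 such fits (highest adjusted p = 0.0851) and in a fit of only the groups compared (adjusted p = 0.167), and that of IAA2 without GR-KAN1 120 min replicate 1 (adjusted p = 0.0592). Of the 15 abscisic acid genes 1 rose and 2 fell at 60 min and 1 rose and 1 fell at 120 min, with the list not shifted (camera adjusted p = 0.297 and 0.878). The one that rose was ABI2, a protein phosphatase, at 1.1 and 1.01. HFR1 rose by 1.78 beyond WT at 120 min, the time at which it fell in WT.

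The touch and early stress list, high in GR-KAN1 at 0 min, had a median change of -1.26 beyond WT at 30 min (camera adjusted p = 0.0219), and medians of -0.92 and -1.17 at 60 and 120 min that did not pass (adjusted p = 0.147 and 0.191). Of its 11 genes 0 passed limma's test over all genes there, and 6 fell when adjusted over the list alone. The list's call was lost in 5 of 18 fits without a single library (highest adjusted p = 0.235, without GR-KAN1 30 min replicate 3), with WT replicates 4 to 6 left out (adjusted p = 0.0936) and in a fit of only the groups compared (adjusted p = 0.0833). In all, 2 genes rose and 11 fell beyond WT in GR-KAN1 at 30 min, 41 rose and 163 fell at 60 min, and 55 rose and 106 fell at 120 min. Of these, 20 higher and 69 lower genes were shared by 60 and 120 min, again with the same 0 min libraries, and 0 were called the opposite way. Lists of the same sizes shared a mean of 3.51 and 14 genes and at most 12 and 43 in simulated data with no effect. At 30 min 13 became 3 without GR-KAN1 0 min replicate 3, 5 without GR-KAN1 0 min replicate 2 or GR-KAN1 30 min replicate 2, 7 without WT 0 min replicate 5 and 8 without WT 30 min replicate 2, 5 or 6 or GR-KAN1 30 min replicate 1. At 60 min 204 became 105 without GR-KAN1 0 min replicate 2, and at 120 min 161 became 91 without GR-KAN1 120 min replicate 1 and 92 without GR-KAN1 0 min replicate 2. At 60 min 113 genes were called with no code series covariate and 104 with WT replicates 4 to 6 left out, and at 120 min 327 in a fit of only the groups compared. The count at 30 min also moved in several settings, up with quantile normalization and down with only the groups compared, as given in the part on processing.

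**Figure D4:**
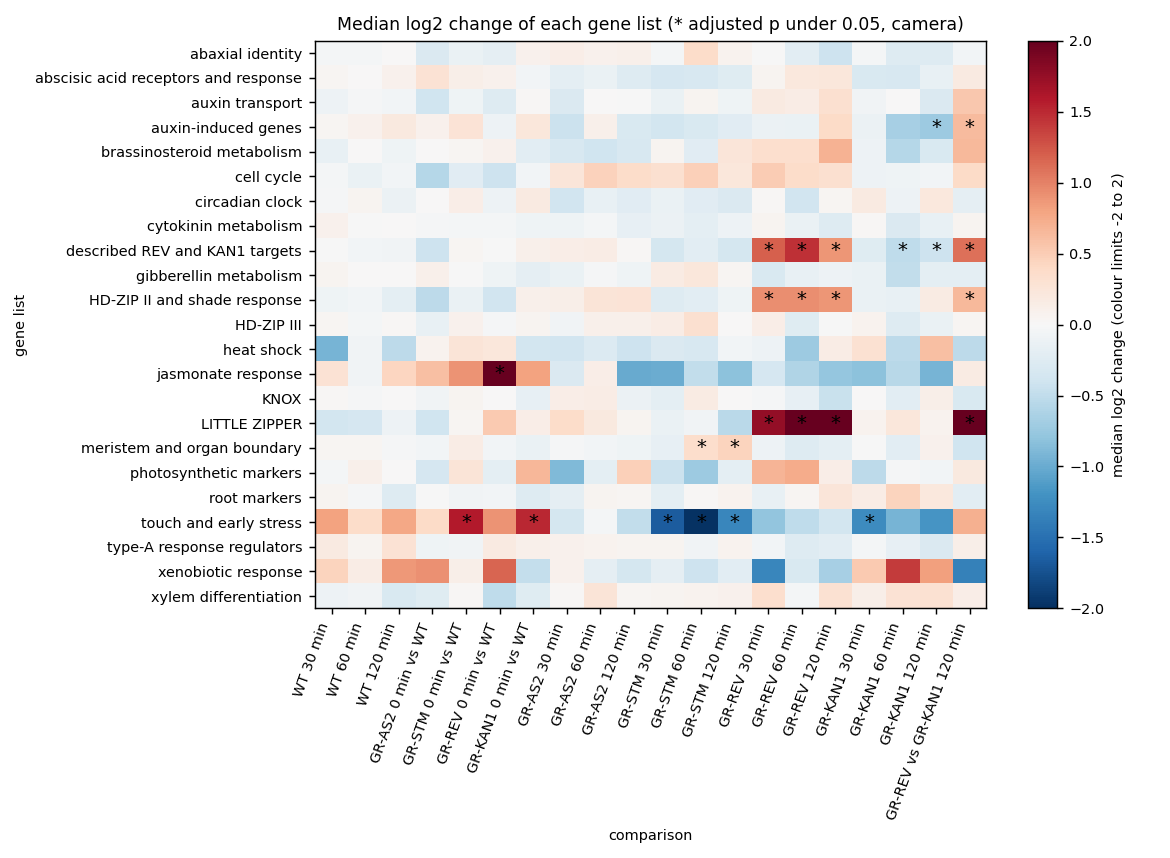
Median log2 change of each of the 23 gene lists (horizontal axis comparisons, vertical axis lists, colour for the median), with marks where camera with an estimated correlation gave an adjusted p under 0.05. The marks are 25 of 460, among them the LITTLE ZIPPER list in GR-REV with medians of 1.76, 4.16 and 3.6.

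REV and KAN1 are known as factors of opposite leaf sides, and the changes in their lines at 120 min were compared directly. ZPR1 rose in GR-REV relative to GR-KAN1 by 5.19 on the log2 scale (SE 0.39, limma adjusted p = 3.04e-14), with 1510 ± 485 FPKM in GR-REV and 26.6 ± 2.66 FPKM in GR-KAN1 at 120 min (SD, n = 3 each). HAT2 differed by 2.1 (SE 0.26), PYL6 by 2.22 (SE 0.32), TAA1 by 1.40 (SE 0.23) and DWF4 by 1.46, each higher in GR-REV. CYS2 differed the other way (-4.16, SE 0.42, adjusted p = 8.99e-10), at 3.47 ± 0.474 FPKM in GR-REV and 64.0 ± 25.4 FPKM in GR-KAN1. So did MES10 (-3.05, SE 0.36), GA20OX3 (-2.52), HAI1, a phosphatase of abscisic acid signalling (-2.22), and CIB1, a bHLH partner of cryptochrome (-3.27, SE 0.61). CRK30 and RTFL12, both lower in GR-KAN1, differed by 2.96 (SE 0.36) and 2.86 (SE 0.62).

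Of the 4 LITTLE ZIPPER genes 3 were higher in GR-REV and 0 in GR-KAN1, 3 also when adjusted over the list alone, with a median of 4.04 (camera adjusted p = 3.55e-08). Of the 12 described targets 7 were higher in GR-REV, 9 over the list alone, with a median of 1.11 (adjusted p = 8.75e-11). Of the 13 auxin-induced genes 4 were higher in GR-REV, 6 over the list alone, with a median of 0.64 (adjusted p = 0.0138). These included the Aux/IAA genes IAA1, at 1.82 (SE 0.39), IAA2, at 1.56 (SE 0.28), and IAA19, at 1.65 (SE 0.36). Of the 12 HD-ZIP II and shade genes 3 were higher in GR-REV, 6 over the list alone, with a median of 0.65 (adjusted p = 0.0233). That list's call was lost without GR-REV 0 min replicate 1 or GR-REV 120 min replicate 2 (highest adjusted p = 0.0803) and in a fit of only the groups compared (adjusted p = 0.0546). In all, 266 genes were higher in GR-REV and 253 in GR-KAN1, and 2464 had an unadjusted p under 0.05 in limma. The 519 became 335 without GR-REV 0 min replicate 3, 323 without GR-KAN1 0 min replicate 1 and 334 without GR-KAN1 0 min replicate 2. They became 277 with no code series covariate, 314 among genes with a mean of 5 FPKM or more and 188 in a fit of only the groups compared.

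**Figure D5:**
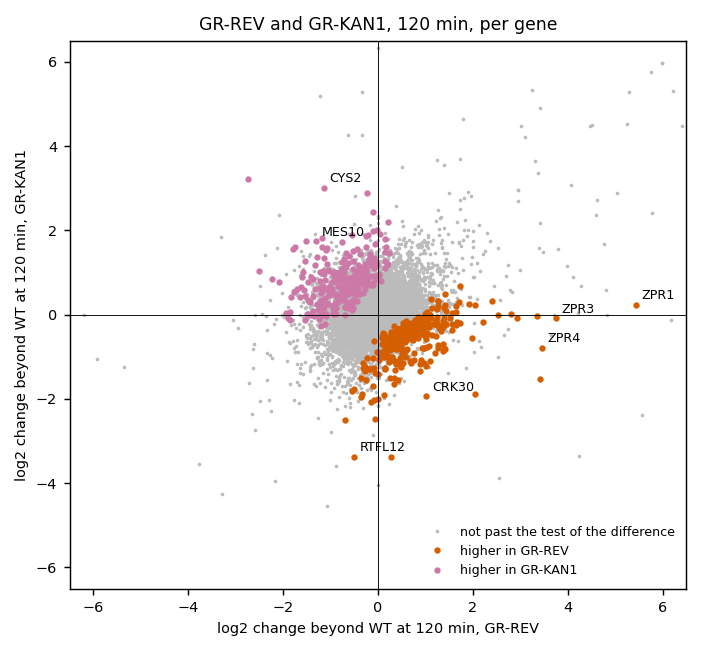
Log2 change beyond WT at 120 min per gene in GR-REV (horizontal axis) and GR-KAN1 (vertical axis) for 19383 genes, with colour for the 266 higher in GR-REV and the 253 higher in GR-KAN1 in limma's test. ZPR1 lies at 5.43 in GR-REV, and 23 genes outside the axes, 0 of them past the test, are not drawn.

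Of the 460 tests of lists, 18 shifts were upward and 7 downward, all with an estimated correlation, and 104 passed with the preset correlation of 0.01. In fits of only the groups compared, 12 of the 25 list calls were lost. These were all 6 of the touch and early stress list, jasmonate in GR-REV before dexamethasone, meristem and organ boundary in GR-STM at 60 and 120 min, described targets and auxin-induced genes in GR-KAN1 at 120 min, and HD-ZIP II and shade between GR-REV and GR-KAN1 (adjusted p from 0.0546 to 0.756). In no comparison did 16 of the 23 lists shift. The smallest adjusted p of each was 0.0608 for abaxial identity, 0.0608 for abscisic acid, 0.0655 for KNOX, which holds STM itself, 0.0775 for heat shock, 0.0837 for brassinosteroid metabolism, 0.0959 for cell cycle, 0.124 for cytokinin metabolism and 0.166 for auxin transport. It was 0.166 for gibberellin metabolism, 0.166 for xenobiotic response, 0.191 for type-A response regulators, 0.284 for xylem differentiation, 0.344 for circadian clock, 0.377 for root markers, 0.440 for photosynthetic markers and 0.472 for HD-ZIP III. Of the seed storage list 1 gene was measured, which passed limma's test in 0 of the 20 comparisons.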

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

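Of the tests in this part, the splits drawn after each line's mean was taken out were chosen after the result was seen. Dixon's test was run in WT on 11 genes, the 4 targeted genes and 7 that the rule for named genes took by size of change in WT. Of the 44 groups of 6 libraries, 6 had a library further from the others than Dixon's 95% critical value, where chance gives about 1 in 20, or 2.2 groups. IGMT2 stood at 59.2 FPKM in WT 30 min replicate 3, with 11.9 FPKM in the nearest library, and at 36.2 FPKM in WT 60 min replicate 4, with 14.4 FPKM in the nearest. CYP81F2, of the same indole glucosinolate pathway, stood highest in these 2 libraries as well, at 9.71 FPKM in WT 30 min replicate 3 and 11 FPKM in WT 60 min replicate 4. AT2G44130 stood at 14.7 FPKM in WT 0 min replicate 1 and at 85.3 FPKM in WT 120 min replicate 2.

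The change from 0 to 120 min differed between GR-REV and GR-KAN1 in 519 genes, by limma's test of the difference itself. Of 100 splits of the same libraries, 13 called as many genes, the real one included, with up to 3716 in another split. These splits exchanged libraries between the lines at each time separately. A lasting difference between the lines can then enter another split as a change over time, so these counts cannot decide on chance. After each line's mean was taken out, 1 of 100 splits, the real one, called as many, and the highest other called 246. That setting was chosen after the result was seen, so chance is not called excluded.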

How the results depend on the processing

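Of the settings in this part, the log10 FPKM total as a covariate, the fit without the 2 libraries least like the rest, the leaving out of each library for named genes and called lists, and the correlation of own changes were chosen after seeing the data. No setting called a named gene in the opposite direction, but 131 of 319 named calls were lost with WT libraries 4 to 6 left out and 131 with only the groups compared, and 156 were kept in every fit without a single library. With no filter on low values, with a block for replicate number or with the FPKM total as a covariate, 0 of the 20 counts of genes moved by over 1.5 times, but 17, 22 and 20 of the 319 named calls were lost. Of the 25 list calls 12 were lost with only the groups compared, 2 each with WT libraries 4 to 6 left out, with a replicate block within line (of 22) and with the FPKM total as a covariate, and 1 each with pseudocount 1, no filter, the filter at 5 FPKM and the 2 least typical libraries left out. Those lost in more than 1 of these settings were the touch and early stress list in GR-STM at 120 min and in GR-KAN1 at 30 min, auxin-induced genes and described targets in GR-KAN1 at 120 min, and HD-ZIP II and shade between GR-REV and GR-KAN1. Replicate numbers showed no general pairing of the samples. Over 31 pairs of groups, each with 0 min or with WT, the residual correlations had a median of -0.0035 (-0.386 to 0.409). In 0 pairs was every correlation above 0.1, a strict rule that cannot exclude pairing in some groups. Depth is unknown, so no limit from counting could be set. Unless said, the cause of a difference was not tested.

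With no library code series covariate, WT genes changed were 2 at 30 min and 273 at 120 min, genes changed before dexamethasone were 137 in GR-STM, 2410 in GR-REV and 308 in GR-KAN1, and genes changed beyond WT were 0 and 1 in GR-AS2 at 60 and 120 min and 113 in GR-KAN1 at 60 min, with 277 genes differing between GR-REV and GR-KAN1.

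With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, WT genes changed were 0, 9 and 175 at 30, 60 and 120 min, and genes changed before dexamethasone 114 in GR-AS2, 4 in GR-STM and 573 in GR-REV. Beyond WT they were 15 and 2 in GR-AS2 at 60 and 120 min, 0 in GR-STM at 30 min, 2, 112 and 84 in GR-REV at 30, 60 and 120 min, and 4 and 327 in GR-KAN1 at 30 and 120 min. Genes differing between GR-REV and GR-KAN1 were 188, and gene list shifts 13.

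With WT libraries 4 to 6 left out, which leaves 3 WT libraries per time, WT genes changed at 60 min were 2, and genes changed before dexamethasone 304 in GR-AS2, 15 in GR-STM, 826 in GR-REV and 43 in GR-KAN1. Beyond WT they were 1 in GR-AS2 at 120 min, 1, 42 and 95 in GR-STM, 4, 77 and 68 in GR-REV at 30, 60 and 120 min, and 2 and 104 in GR-KAN1 at 30 and 60 min.

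With quantile normalization, WT genes changed were 10 at 60 min and 26 at 120 min, and genes changed beyond WT 8 in GR-AS2 at 60 min and 34 in GR-KAN1 at 30 min. With the 2 libraries least like the rest left out, WT genes changed were 10 at 60 min and 29 at 120 min, genes changed before dexamethasone 99 in GR-STM and 942 in GR-REV, and beyond WT 4 in GR-AS2 at 60 min. Among genes with a mean of at least 5 FPKM, which are fewer, WT genes changed at 120 min were 7, before dexamethasone 984 in GR-REV and 80 in GR-KAN1, beyond WT 89 and 71 in GR-STM at 60 and 120 min, 3, 119 and 87 in GR-REV at 30, 60 and 120 min and 8 in GR-KAN1 at 30 min, and 314 differed between GR-REV and GR-KAN1. With pseudocount 0.1 GR-AS2 had 1 gene changed beyond WT at 30 and 1 at 120 min, and with pseudocount 1 it had 1 at 60 min. With a replicate block within line, genes changed beyond WT were 1 in GR-AS2 at 60 min, 14 in GR-STM at 30 min and 7 in GR-KAN1 at 30 min. With the preset correlation gene list shifts were 104.

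Without a single library (leave-one-out), WT genes changed ranged from 1 to 19, 3 to 9 and 5 to 16 at 30, 60 and 120 min. Genes changed before dexamethasone ranged from 25 to 3279 in GR-AS2, 4 to 165 in GR-STM, 760 to 1839 in GR-REV and 45 to 125 in GR-KAN1. Beyond WT at 30, 60 and 120 min they ranged from 0 to 387, 1 to 27 and 0 to 1 in GR-AS2. In GR-STM they ranged from 1 to 105 at 30 min, 77 to 255 at 60 min and 107 to 209 at 120 min. In GR-REV they reached 16 at 30 min in fits that kept both libraries of that time, and ranged from 134 to 260 at 60 min and 97 to 159 at 120 min. In GR-KAN1 they ranged from 3 to 19, 105 to 231 and 91 to 166, and from 323 to 487 for GR-REV against GR-KAN1.

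The relation between the lines' responses at 120 min changed with the WT libraries. As reported, correlations across genes were 0.463 for GR-AS2 and GR-STM, 0.544 for GR-AS2 and GR-REV, 0.369 for GR-AS2 and GR-KAN1, 0.501 for GR-STM and GR-REV, 0.472 for GR-STM and GR-KAN1 and 0.503 for GR-REV and GR-KAN1. In simulated data with no effect and the same shared WT libraries the means were 0.413, 0.439, 0.455, 0.432, 0.397 and 0.418 and the highest values 0.71, 0.803, 0.728, 0.805, 0.751 and 0.679, so these correlations lay within what no effect gives. In the same order they were -0.119, -0.049, -0.104, -0.057, 0.004 and 0.025 with the WT libraries split into 2 sets, so that none was shared, and 0.295, 0.263, 0.006, 0.199, 0.163 and 0.109 for each line's own change. One set of the split was WT replicates 4 to 6, of code series Ot86 at 0 min and OtA0 at 120 min, with no covariate used. Its change is confounded with code series, so the split values do not show the effect of sharing alone.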

Other observations

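Of the tests in this part, the test of action before dexamethasone in GR-AS2, those of neighbouring genes, the splits with each line's mean taken out and the simulated overlaps were chosen after the result was seen. Lists of called genes were compared between lines with lists of the same sizes from 100 simulated sets with no effect, since all lines were set against the same WT libraries. Of 108 genes lower beyond WT in GR-STM at any time and 201 in GR-KAN1, 23 were shared, where the simulated mean was 10.9 and 7 of 100 sets reached 23, so the shared libraries alone were not excluded. They included RTFL12, CAF1a and TCH4, and MYB77, a MYB protein of auxin responses. Between genes higher in GR-REV (170) and lower in GR-KAN1 (201), 10 were shared, among them PYL6 and HAT2, against a simulated mean of 0.62, and 0 of 100 sets reached 10. Between genes lower in GR-REV and higher in GR-KAN1 4 were shared, among them MES10 and MYB7, against a simulated mean of 0.23, and 1 of 100 sets reached 4. Opposite sharing was not particular to these lines. GR-STM lower and GR-KAN1 higher genes shared 3 (mean 0.10, 0 of 100 sets), GR-STM higher and GR-KAN1 lower 6 (mean 0.69, 2 of 100), and GR-STM lower and GR-REV higher 4 (mean 0.34, 2 of 100). For the 13 genes lower in both GR-REV and GR-KAN1, 30 of 100 sets shared as many.

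The touch and early stress list fell beyond WT in GR-STM at 3 times and in GR-KAN1 at 30 min, with medians in GR-KAN1 of -1.26, -0.92 and -1.17 at 30, 60 and 120 min (adjusted p = 0.0219, 0.147 and 0.191). With log10 FPKM total as a covariate the median at 120 min in GR-STM was -1.346, against -1.312 without it, so the total as a covariate did not account for the fall there. This cannot decide on libraries dominated by very short genes, because the total does not measure their share. WT 30 min replicate 1 had a total of 28396648 with 0.12% in genes under 150 bp, and GR-KAN1 120 min replicate 3 had 8915906 with 71.41%. GR-STM and GR-KAN1 started above WT by medians of 1.59 and 1.51 and at 120 min stood 0.103 and 0.354 above it. GR-STM lay below WT in between (-0.16 at 30 min and -0.33 at 60 min, where all 11 genes lay below). At 0 min all measured members but DREB2A and CBF2 were above WT in GR-REV and GR-AS2 too. Of these only ERF6 in GR-REV passed limma's test (adjusted p = 0.0234). In WT the mean FPKM of all 11 genes was higher at 30 min than at 0 min, though the list was not shifted. The high start is thus relative to WT 0 min libraries that all lines share. A candidate explanation for part of the fall is that the 0 min libraries of GR-STM and GR-KAN1 started high against these. A lowering by the activated factor cannot be told apart from this by the value of 0.354, because a lowering from a raised start also ends at the WT level, and the bound set in advance was wrong for that reason.

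GR-AS2 differed from WT in 2000 genes before dexamethasone and in few beyond WT after it. The median residual SD of its libraries was 1.166 times that of GR-STM, under the bound set in advance for a wider spread, and GR-REV had a ratio of 1.156 and many calls. A median over genes and times cannot show a single library that hid changes. The count beyond WT at 30 min went from 0 to 387 without GR-AS2 30 min replicate 2 and to 138 without GR-AS2 0 min replicate 1, so a wider spread stays open. That the 0 min libraries alone stand apart cannot be told apart from a lasting difference. The median difference at 120 min was 0.342 of that at 0 min, while 1777 of the 2000 genes (88.8%) kept their direction. The genes called against WT were 2000, 786, 61 and 21 at 0, 30, 60 and 120 min. The 2000 genes were chosen by their difference at 0 min, so a smaller later difference is partly expected from that choice. The same ratio was 0.543 in GR-REV, 0.223 in GR-KAN1 and 0.133 in GR-STM. Action of the fusion before dexamethasone stays open too. The abaxial identity and KNOX lists had means of -0.31 (95% interval of the list mean over libraries -0.46 to -0.15, camera adjusted p = 0.265) and -0.13 (-0.34 to 0.07, adjusted p = 0.719), but only some members are known targets of AS2, and of these KNAT1, KNAT2 and KNAT6 stood at -0.04, 0.04 and 0.07.

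Pairs of neighbouring genes were at least 2 higher on the log2 scale in a GR line than in WT at all 4 times. Of 5 such pairs, 3 were copies of one gene family, such as VSP1 and VSP2, and 1 had coordinates that overlap, so neither accounts for all pairs. The 2 pairs not of one family were AT4G19239 with AT4G19240 in GR-AS2 and MRD1 with HEI10 in GR-KAN1, of which only the former does not overlap. Of 10000 random draws, 413 held at least 1 neighbouring pair. Each draw pooled sets of all 4 lines' sizes, 29 of 34 genes being those of GR-REV, and did not leave out family pairs. The share therefore does not give the chance of a pair among the 2 genes of GR-AS2. A segment of the genome at one site carried by the line stays open, since these pairs prompted the idea and the nearest measured genes on each side were near WT (CYP707A1 0.02 and EMB3006 0.06 in GR-AS2, AT1G53460 -0.09 and MUM4 -0.17 in GR-KAN1). For MRD1 and HEI10 the overlap leaves it uncertain whether both genes were raised.

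Other splits of the same libraries into groups of the same sizes were counted for each comparison, the real split included. For WT, 1, 4 and 1 of 100 splits called as many genes at 30, 60 and 120 min (real 11, 5 and 13, highest other 3, 114 and 1). What raised the count to 114 in another split at 60 min was not tested. Before dexamethasone, 2 of 84 splits called as many in GR-AS2 (real 2000, highest other 3989), 2 in GR-STM (64 and 71), 1 in GR-REV (1515 and 596) and 1 in GR-KAN1 (144 and 6). All these shares lay under the limit set in advance. With 20 comparisons and no correction over them, this does not exclude chance.

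Beyond WT at 30, 60 and 120 min, 3, 1 and 3 of 100 splits called as many in GR-STM (real 28, 170 and 159, highest other 428, 158 and 263), and 1, 4 and 4 in GR-KAN1 (real 13, 204 and 161, highest other 3, 513 and 939), all under the limit. The limit was reached in GR-AS2 at 60 min, where 8 splits did (real 2, highest other 2301), and in GR-REV, where 9 and 5 did at 60 and 120 min (real 229 and 155, highest other 2257 and 1674). These splits exchanged libraries between a line and WT at each time separately. A lasting difference between line and WT can then enter another split as a change over time. Reaching the limit therefore does not show that chance alone gives as many genes. With each line's mean taken out, as given below, the highest other counts were lower except in GR-KAN1 at 30 min, and stayed high in GR-AS2. What else raised them was not tested. In GR-AS2 at 30 and 120 min the real count is 0, which all 100 splits reach by construction, so the splits decide nothing there (highest other 3326 and 3067). GR-REV at 30 min has 2 libraries and was not tested by splits.

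With each line's mean taken out, 3, 1 and 1 of 100 splits called as many in GR-STM (highest other 71, 100 and 28), 2 and 1 in GR-REV at 60 and 120 min (291 and 109) and 1, 1 and 2 in GR-KAN1 (4, 3 and 181). In GR-AS2 2 splits did at 60 min (highest other 1475), and at 30 and 120 min the count of 0 again decides nothing (all 100 splits, highest other 2265 and 1701). These splits were chosen after the result was seen. They therefore do not replace the splits set in advance, which reached the limit in GR-REV at 60 and 120 min and in GR-AS2 at 60 min. The splits set in advance also hold lasting differences between line and WT, so neither set decides on chance there.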
